A study of Mus musculus with 9 samples.

How the data were processed

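Pancreatic islets, the clusters of endocrine cells that make insulin and other hormones, were isolated from female mice that were virgin or at day 14.5 of gestation (GD14.5). Bulk RNA sequencing gave 5 virgin and 4 GD14.5 libraries, numbered 1 to 5 and 1 to 4 within their groups. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was enriched on oligo(dT) beads, and libraries were amplified by PCR. The genome build was GRCm38.p6, per the submitters' processing notes. The aligner, the transcript quantifier, the annotation and the strand setting are not given in the sources used here. The labels do not say whether a library came from 1 animal or from several, so the p-values measure the spread between these libraries.

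The values are FPKM (fragments counted at a transcript, divided by its length and by the fragments of the library), which the authors deposited for all 9 libraries, rounded to 2 decimals, with 1 line per transcript and a gene name but no transcript identifier. The table used here held 26375 transcripts under 10962 names. Of these, 480 transcripts carried a numeric suffix that marks a copy on another sequence of the assembly, and they were left out. Of the 10706 remaining names, 10705 matched a gene symbol of the RefSeq annotation of GRCm38.p6. RefSeq classes 9300 of them as long noncoding RNA genes, 1284 as coding genes and 99 as pseudogenes. Messenger RNAs of most coding genes, among them the islet hormones, are not analysed here. A line under a coding gene's name was read as a transcript at that locus of unknown identity. Among the tested names of coding genes, 451 of 579 have no noncoding transcript in RefSeq, so their signal cannot be told from reads of the gene's messenger RNA or its precursor.

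FPKM of transcripts with the same name were summed, and a name is called a locus below. Loci with a mean FPKM over the 9 libraries of at least 0.5 were tested, 2377 in all. Coordinates are those of the RefSeq genes on GRCm38.p6, counted from 1. The depth of the libraries is unknown. Low values were searched for steps of whole reads in short loci with 1 transcript, and no step was resolved. The strongest step was above the 95% level of 100 jittered copies in 4 of 9 libraries and above their maximum in 0. The summed FPKM of the table ranged from 5415.3 to 20530.6 between libraries. Because FPKM divides by transcript length, this range does not show which total the unit scales to. A fold change as deposited carries these differences between libraries, whether they come from library scaling or from the RNA itself.

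GD14.5 was compared with virgin on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided), and p was adjusted by the Benjamini-Hochberg method over the 2377 loci with a threshold of 0.05. A fold change on this scale understates the change of loci with low values. This design, the threshold, 37 gene lists and most of the alternatives were set before the data were examined. It foresaw a table of all genes, and it was kept for the noncoding table. Kmt5a and the 4 loci past the threshold also had a two-sided exact permutation test over all 126 splits of the libraries, for which 0.00794 is the smallest p. Gene lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Of the 676 distinct list genes, 28 had a line in the table and 12 were tested, and only the list of histone and DNA methyltransferases had enough members. Loci at a list gene or within 20 kb of one were therefore tested as neighbours of 18 lists, a set of tests chosen after the leading loci had been seen. A further 6 classes of loci were also compared. They were set from name patterns or, for loci with the name of a coding gene, from the RefSeq class. This was done after the content of the table was known and before they were tested.

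The replicate numbers are shared by the groups, and the labels do not say that they pair libraries. After each group's mean was removed, the deviations of same-numbered libraries correlated across loci at 0.49, 0.20, 0.28 and 0.59 for numbers 1 to 4, while the 12 pairs of virgin 1 to 4 with GD14.5 libraries of other numbers gave −0.55 to 0.25. Virgin replicate 5 correlated at 0.49 with GD14.5 replicate 4, as high as the same-numbered pair of number 1. Virgin replicate 2 correlated at 0.23 with GD14.5 replicate 1, above its 0.20 with the same number. All 4 same-numbered correlations were above 0.1, a limit for pairing written after the data were seen. That limit does not single out the shared number as a pairing. The fit with the replicate number as a block is printed beside results that it changes. Virgin replicate 5 has no partner and does not enter the fold changes of that fit; without it the fit called 23 loci higher and 4 lower, against 23 and 3 with it. After their values were seen, the libraries were put into 3 sets by number, number 1, numbers 2 and 3, and numbers 4 and 5. No label gives these sets. Differences were also taken within each set.

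The analysis was tested on simulated data made from the real residuals of the 2377 loci, with 200 loci changed in each of 5 rounds. Without the block, 93.6% of loci changed by 2 on the log2 scale were recovered and 0% of those changed by 1. With the replicate block these shares were 99.4% and 89.6%, with a mean of 3 unchanged loci called per round. With equal library medians and no block they were 95.0% and 79.2%, with 0 unchanged loci called. Each group's mean was removed from the residuals, so before any scaling an unchanged locus had a group difference of 0 by construction. The shares therefore leave out the chance spread of group means, and they do not measure power or false calls in the real data.

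The loci named were set by a rule: the 10 largest rises and falls past the threshold with a mean FPKM of at least 1 and groups that do not overlap, leaving out predicted genes; up to 4 members past the threshold of each described list, or the 2 most abundant where none passed; and always Hbegf, Egfr, Kmt5a, Ins1, Ins2, Gcg, Sst, Prlr, Tph1, Tph2 and Mki67. The rule named Ivd, Cish, Kmt5a, Dnmt3a, Suz12 and Prlr, while Hbegf, Egfr, Ins1, Ins2, Gcg, Sst, Tph1, Tph2 and Mki67 are not analysed here. All other loci in the text were chosen after their values were seen. The alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, the replicate block and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.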

Results

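Transcript levels in islets of virgin and pregnant mice were measured by bulk RNA sequencing, with 5 virgin libraries and 4 libraries from pregnant mice at GD14.5. The values used here are FPKM of transcripts that mostly belong to long noncoding RNA genes. Of the 2377 loci tested, RefSeq classes 1768 as long noncoding RNA genes, 579 as coding genes and 23 as pseudogenes. The most abundant was Malat1, a nuclear noncoding RNA on chromosome 19 (5795690 to 5802672, GRCm38.p6), at 2667 ± 1870 FPKM in virgin islets (SD, n = 5) and 1848 ± 988 at GD14.5 (SD, n = 4). Malat1 took 16.6% to 25.3% of the summed FPKM of a library. The imprinted noncoding RNA Meg3 stood at 122 ± 65.3 and 93.0 ± 42.6 FPKM, and Neat1, the scaffold of nuclear paraspeckles, at 153 ± 113 and 136 ± 52.5 FPKM.

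Summed over all names, the libraries held 12360 ± 6750 FPKM in the virgin group (SD, n = 5) and 9375 ± 3599 at GD14.5 (SD, n = 4). The groups did not differ in the logarithm of this sum beyond the spread of the libraries (difference −0.28 on the log2 scale, exact permutation p = 0.571). Within groups it varied 3.79 times among virgin and 2.26 times among GD14.5 libraries, and it was highest in virgin 4, virgin 5 and GD14.5 replicate 4. The first principal component, with 72.2% of the variance, set those 3 libraries apart from the other 6. The depth behind these values is unknown.

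**Figure D1:**
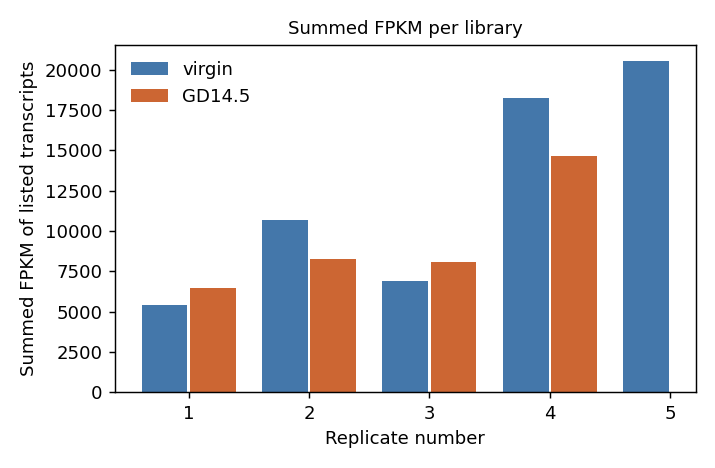
Summed FPKM of the listed transcripts (vertical axis) in each library by replicate number (horizontal axis), with virgin in blue and GD14.5 in orange. Virgin 4, virgin 5 and GD14.5 replicate 4 reach 18252, 20531 and 14636 FPKM, and the other 6 libraries lie between 5415 and 10689.

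The first comparison asked which loci differ between GD14.5 and virgin islets. The largest difference on the log2(FPKM + 0.5) scale was at Ivd, which encodes a mitochondrial enzyme of leucine breakdown (chromosome 2, 118861959 to 118882909). Its transcript was at 0.210 ± 0.305 FPKM in virgin islets (SD, n = 5) and at 12.6 ± 3.68 FPKM at GD14.5 (SD, n = 4), a log2 fold change of 4.26 ± 0.41 (SE; limma adjusted p = 9.04e-07). At Cish, a STAT5 target that restrains cytokine receptor signalling (chromosome 9, 107296659 to 107302784), it rose from 2.97 ± 0.989 to 29.1 ± 10.8 FPKM, with a log2 fold change of 3.07 ± 0.49 (SE; limma adjusted p = 0.00207). The long noncoding RNA gene Gm33391 (chromosome 8, 86921205 to 86926374) rose from 0.284 ± 0.212 to 5.70 ± 3.09 FPKM (log2 fold change 2.91 ± 0.39, SE; limma adjusted p = 1.42e-04). Gm13715, a long noncoding RNA gene 9.69 kb from Lrrc55 (chromosome 2, 85208436 to 85243678), rose from 0.0760 ± 0.143 to 7.41 ± 10.8 FPKM (log2 fold change 2.93 ± 0.52, SE; limma adjusted p = 0.00682). GD14.5 replicate 4 was at 23.65 FPKM at Gm13715 and the other 3 GD14.5 libraries at 1.19 to 2.43, and without replicate 4 the log2 fold change was 2.10.

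At each of these 4 loci all GD14.5 libraries were above all virgin libraries, and the exact permutation p was 0.00794, the smallest that 126 splits allow. These loci were picked by limma in the same libraries, and this p is not adjusted over the 2377 loci. The separation, this p and the differences within sets that follow are therefore not separate support. The differences held within the 3 sets of replicate numbers, at 4.46, 3.72 and 4.74 on the log2 scale for Ivd, 2.10, 3.50 and 3.44 for Cish, 2.69, 2.90 and 3.49 for Gm33391 and 2.46, 2.11 and 5.23 for Gm13715. The call of Gm13715 was lost without virgin replicate 1 (limma adjusted p = 0.218; log2 fold change 2.90) and with the replicate block on equal library medians (limma adjusted p = 0.147; log2 fold change 3.18).

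**Figure D2:**
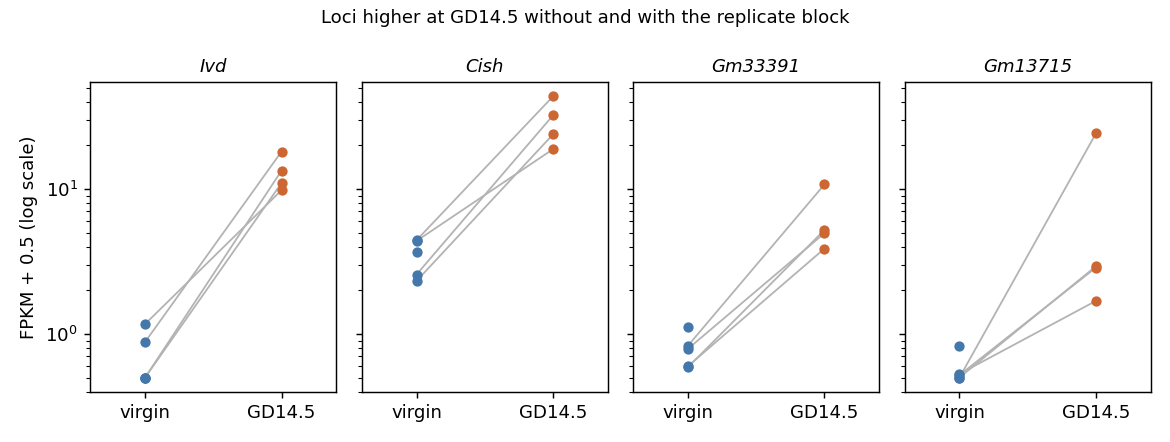
FPKM + 0.5 on a logarithmic axis at Ivd, Cish, Gm33391 and Gm13715, with 1 point per library (blue, virgin; orange, GD14.5) and lines that join libraries with the same replicate number; the virgin point without a line is replicate 5. Every GD14.5 library lies above every virgin library at the 4 loci, for Cish between 18.3 and 43.0 FPKM against 1.82 to 3.93.

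Without the block, limma called these 4 loci higher at GD14.5 and 0 lower, with 26 loci higher and 34 lower at an unadjusted p under 0.05. With the replicate block it called 23 higher and 3 lower, with 83 higher and 138 lower at an unadjusted p under 0.05, and the 4 loci were among the 23. Scaling also moved the counts, to 22 higher and 1 lower with equal library medians, 25 and 6 with equal totals, and 24 and 5 after quantile normalization. The median log2 fold change over all loci was −0.30 as deposited, −0.13 with the block and −0.02 with equal medians, so a locus at −0.30 without the block lay at the middle of the table.

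Among the loci called with the replicate block and not without it on the values as deposited, several lie beside genes of known function. The 4 loci that follow were also called without the block on equal library medians. The noncoding locus 5730420D15Rik starts 54 bp from Socs2, a further cytokine-induced suppressor of receptor signalling, on chromosome 10 (95417375 to 95428640). It rose from 0.674 ± 0.528 FPKM (SD, n = 5) to 2.87 ± 2.27 (SD, n = 4), with a blocked log2 fold change of 1.62 ± 0.18 (SE; limma adjusted p = 3.91e-04, and 0.735 without the block). The locus 1300002E11Rik, 6.51 kb from the peroxisomal fatty acid oxidation gene Ehhadh on chromosome 16 (21794347 to 21809040), rose from 10.05 ± 7.53 to 23.9 ± 17.7 FPKM (blocked log2 fold change 1.60 ± 0.22, SE; limma adjusted p = 0.00201, and 0.817 without the block). Gm14636, 9.5 kb from Mir222 and 10.1 kb from Mir221 on chromosome X, had a blocked log2 fold change of 1.78 ± 0.19 (SE; limma adjusted p = 3.38e-04). Gm26684 lies 159 bp from Enpp2, which encodes the lysophospholipase autotaxin, and had 1.41 ± 0.20 (SE; limma adjusted p = 0.00201). Without the block, limma's adjusted p was 0.817 for Gm14636 and 0.735 for Gm26684, and with the block on equal medians the call of Gm26684 was lost (log2 fold change 1.52; limma adjusted p = 0.0788).

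A group of 3 loci lies inside Kirrel3, a gene of an immunoglobulin-like adhesion protein on chromosome 9 (34485853 to 35040807). With the block, Kirrel3os rose by 1.93 ± 0.20 on the log2 scale (SE; limma adjusted p = 2.48e-04), Gm45955 by 1.78 ± 0.22 (limma adjusted p = 7.46e-04) and Gm33561 by 1.79 ± 0.22 (limma adjusted p = 9.34e-04). Their FPKM went from 2.85 ± 2.41, 3.16 ± 2.67 and 3.23 ± 2.77 (SD, n = 5) to 9.50 ± 7.50, 8.65 ± 5.04 and 8.91 ± 5.02 (SD, n = 4). At Kirrel3os, GD14.5 replicate 4 was at 20.69 FPKM and the other GD14.5 libraries at 5.02 to 6.87. Without replicate 4 its log2 fold change without the block was 1.21, against 1.65 with it. Overlapping antisense signal cannot be separated here, because the strand setting is not given in the sources used here.

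Rises of coding-gene names with the block also included Lonrf3 (1.44 ± 0.17, SE; limma adjusted p = 7.46e-04) and Gsdma, a gasdermin gene (1.14 ± 0.21, SE; limma adjusted p = 0.0192). Gsdma was not called with the block on equal medians (log2 fold change 1.24, limma adjusted p = 0.151). The remaining 10 rises, at noncoding loci and a pseudogene, had blocked log2 fold changes from 0.81 at Gm41349 to 2.14 at Gm13456. The 3 loci lower with the block were Cdc42ep1, an effector of the GTPase Cdc42, at −1.51 ± 0.29 (SE; limma adjusted p = 0.0230), the transcription factor gene Hivep2 at −1.64 ± 0.32 (limma adjusted p = 0.0252) and the noncoding Gm33732 at −0.91 ± 0.19 (limma adjusted p = 0.0441). None of these 3 was called with the block on equal medians, where limma's adjusted p was 0.176, 0.147 and 0.0559. Their log2 fold changes there were −1.40, −1.53 and −0.81. Of the 26 blocked calls, 25 had the same direction in 4 of 4 same-numbered pairs and in each of the 3 sets. The exception was Hivep2, which was lower in 3 of 4 pairs and listed at 0 in both libraries of number 1. The blocked fit draws on the same pair differences, so this agreement is in large part what its threshold selects. Of the 26, 13 were also called with the block on equal medians, and 9 had groups that did not overlap. Over all 2377 loci the groups did not overlap at 0.589%, with GD14.5 above at 10 and below at 4, where random grouping gives 1.59%.

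Leaving 1 library out of the blocked fit left 15 of the 26 calls in place in all 9 fits, among them Ivd, Cish, Gm33391, 5730420D15Rik, 1300002E11Rik, Gm14636 and the 3 loci in Kirrel3. A library whose partner is left out does not enter the blocked fold changes. Leaving out either library of a pair thus gives the same fold changes, so the 9 fits are not 9 separate checks. The calls kept in the fewest fits were Gm33732 and Gm51648 (1 of 9), Gm41349 (2 of 9) and Gsdma (3 of 9). The count of lower loci rose from 3 to 23 without virgin replicate 3 and to 22 without GD14.5 replicate 3, fits that rest on the same pairs. It rose to 5 without virgin replicate 4.

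**Figure D3:**
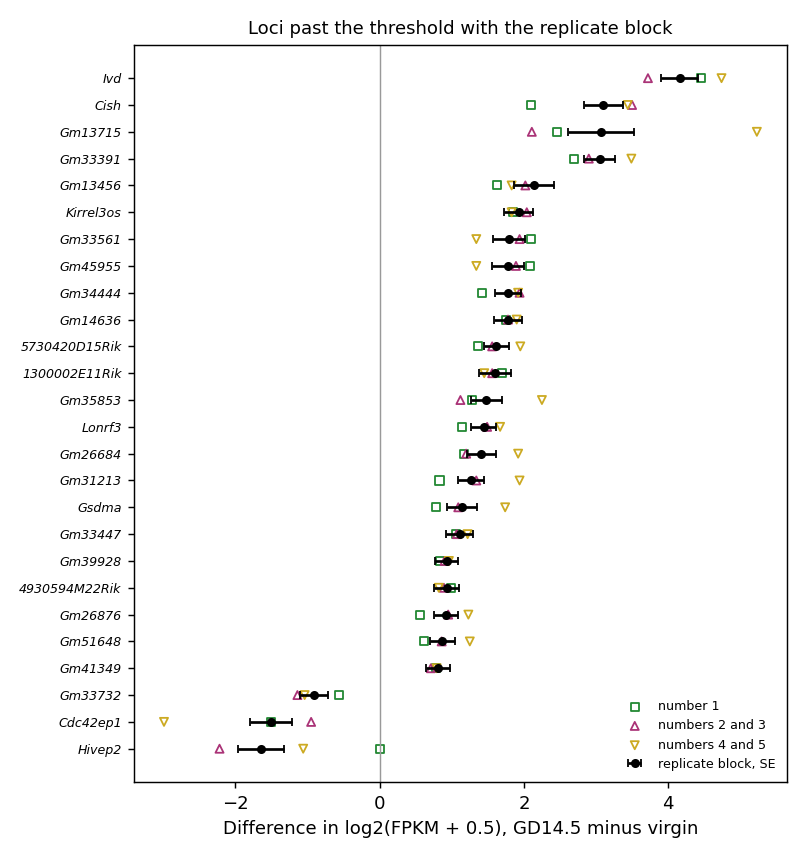
Blocked difference in log2(FPKM + 0.5), GD14.5 minus virgin, with its SE (black) for the 26 loci past the threshold with the replicate block, and the difference within each set of replicate numbers (open symbols). Of the loci, 23 lie above 0 and 3 below, and Hivep2 is at 0 in the set of number 1.

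The study's title names HBEGF, EGFR and Kmt5a, so the second comparison asked whether these genes differ at GD14.5. Hbegf and Egfr are not analysed here. At Kmt5a, whose protein monomethylates lysine 20 of histone H4 (chromosome 5, 124439930 to 124462311), 1 transcript of unknown identity was at 2.31 ± 1.75 FPKM in virgin islets (SD, n = 5) and 1.57 ± 1.08 at GD14.5 (SD, n = 4). Its log2 fold change was −0.37 ± 0.56 (SE; 95% interval −1.53 to 0.79), which did not exceed the spread of the libraries (limma adjusted p = 0.819; exact permutation p = 0.595). Being the only title gene tested, its p adjusted over the list alone was limma's unadjusted 0.518. The interval leaves room for more than a halving as well as a rise, and with the replicate block the fold change was −0.09 ± 0.19 (SE; limma adjusted p = 0.849).

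Histone and DNA methyltransferases were the only list with enough tested members. None of its 6 tested loci, Kmt5a, Suz12, Dnmt3a, Nsd1, Nsd2 and Dot1l, passed the threshold over all loci or adjusted over the list alone, without or with the block. The 2 most abundant were Dnmt3a, which encodes a de novo DNA methyltransferase, at 6.65 ± 3.82 FPKM (SD, n = 5) and 3.55 ± 1.86 (SD, n = 4), and Suz12, of the Polycomb repressive complex, at 3.14 ± 1.90 and 2.67 ± 1.42 FPKM. The mean log2 fold change of the list was −0.38, against a median of −0.30 over all loci, and limma's camera gave an adjusted p of 0.480 as the single list. With an estimated correlation the adjusted p was 0.755, and the p of limma's fry was 0.378.

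Loci at or within 20 kb of genes known to rise in islets with pregnancy or lactogens were compared after the leading loci, Ivd and Cish among them, had been seen, so the tests of this set in part restate those calls. There were 6 such loci, Ivd, Cish, 5730420D15Rik, 1300002E11Rik, Gm41269 and Sergef; 2 were called higher without the block and 4 with it, and 3 and 4 adjusted over the list alone. Gm41269 and Sergef had log2 fold changes of −0.21 ± 0.43 and −0.05 ± 0.39 (SE). Camera over 18 neighbour lists gave an adjusted p of 2.78e-25 without the block and 1.62e-14 with it. With an estimated correlation, 0.384 without the block and −0.0434 with it, the adjusted camera p was 0.00615 and 0.0661. For the neighbours of JAK-STAT5 genes, 3 loci with Cish and 5730420D15Rik shared with the list above, the adjusted camera p was 4.10e-12 and 1.48e-07. With an estimated correlation, 0.651 and −0.297, the adjusted camera p was 0.0168 and 0.0954. For both lists the estimate with the block was below the preset 0.01, so a higher correlation does not account for the larger p there.

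Neighbours of 4 further lists were called by camera without the block and not with it. For branched-chain amino acid breakdown, 1 of 5 loci, Ivd, was called (camera adjusted p = 3.18e-04, and 0.0802 with the block; adjusted p = 0.193 with an estimated correlation). For acinar markers, ductal markers and G1/S regulators, 0 of 4, 0 of 4 and 0 of 9 loci passed limma's threshold over all loci without the block, and the camera adjusted p was 0.0435 for each. With the block it was 0.206, 0.276 and 0.206, and with an estimated correlation the adjusted p without the block was 0.280, 0.697 and 0.697. The ductal neighbour Gm35853, near the keratin gene Krt7, passed without the block when adjusted over the list alone. With the block it passed over all loci (log2 fold change 1.48 ± 0.21, SE; limma adjusted p = 0.00280). That call was lost with the block on equal medians (log2 fold change 1.58, limma adjusted p = 0.103). On equal medians without the block Gm35853 passed (log2 fold change 1.71, limma adjusted p = 0.0187). The other 12 neighbour lists, among them beta cell identity, S phase, mitosis and serotonin genes, were not called without or with the block.

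Prlr, the prolactin receptor gene, had a transcript below the minimum for testing, at 0.116 ± 0.259 FPKM in virgin islets (SD, n = 5) and 0.378 ± 0.349 at GD14.5 (SD, n = 4). The groups overlapped, with values from 0 to 0.580 and from 0 to 0.840 FPKM.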

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

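The tests of what lies behind the summed FPKM were chosen after its values had been seen, and the counts over other splits were planned. Of 64 sets of values, each 1 locus or library measure in 1 group, 8 held a library far from the others by Dixon's criterion, where chance gives about 3.2.

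In 6 of the 8 the library was GD14.5 replicate 4, and it was the highest of its group. Its log2(FPKM + 0.5) was 5.67 at 1300002E11Rik against 3.79 to 4.09 in the other 3 libraries, 2.76 at 5730420D15Rik against 0.97 to 1.25, 3.84 at Gm14636 against 2.03 to 2.16, 2.07 at Gm26684 against 0.42 to 0.66, and 2.47 at Lonrf3 against 0.79 to 0.89. At Malat1 it was 11.70 against 10.30 to 10.52. The other 2 were Gm13715 in virgin replicate 5, at −0.27 against −1 to −0.92 in the other virgin libraries, and Hivep2 in GD14.5 replicate 3, at 0.07 where the other GD14.5 libraries are listed at 0 FPKM.

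The summed FPKM differed several-fold within each group and followed the replicate number, with virgin 4, virgin 5 and GD14.5 replicate 4 highest. A few abundant transcripts do not account for it, since without the 10 most abundant loci the largest sum was still 3.95 times the smallest. Gestation does not either, since the virgin libraries alone differed 3.79 times. Shared handling or sequencing of libraries with the same number is a candidate explanation, with the smallest correlation of deviations among the 4 same-numbered pairs at 0.20; the labels give no batch. A share of noncoding or unspliced RNA that differs between preparations stays open and was not tested, because coding transcripts are not analysed here.

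Other groupings of the libraries show the same structure. Of 100 splits of the 9 libraries into 5 and 4, 5 gave at least the 4 higher loci of the real split, the real one included, so without the block the count does not exclude chance. The highest other split gave 2012 and put virgin 2, virgin 4, virgin 5 and GD14.5 replicate 4 together, which points to a structure of the samples by summed FPKM. With the replicate block, 16 splits part all 4 same-numbered pairs, too few for a share under 0.05. The real split gave 26 changed loci; its mirror, which the blocked fit treats alike, made 2 splits with as many, also 26, and the highest of the other 14 gave 0.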

How the results depend on the processing

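The 3 sets of numbers as a batch term, the library median as a covariate, the block on equal medians, the fit without the 3 largest libraries and the tests of single transcripts were chosen after the data were seen. Ivd, Cish and Gm33391 stayed called in all 26 alternatives run on them, with log2 fold changes of 3.48 to 5.90, 2.86 to 3.54 and 2.30 to 3.96. Gm13715 stayed called in 19 of 24, at 2.10 to 4.67. It lost its call without the filter, without the variance trend, with robust eBayes, without virgin replicate 1 and with the replicate block on equal medians (limma adjusted p 0.0585 to 0.822).

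The 22 loci called with the block and not without it on the values as deposited kept their direction in all 539 combinations of locus and alternative. They were called in 152 of these, 22 with the block itself and 22 with array weights. The blocked fit selected these loci, and the alternatives refit values of the same libraries, so a kept direction was largely set by the selection. The counts of 4 loci higher and 0 lower became 23 and 3 with the replicate block, 25 and 6 with equal totals, 22 and 1 with equal medians, and 24 and 5 after quantile normalization. They were 15 and 0 with the block on equal medians, 27 and 6 with the batch term, 30 and 3 with the covariate, and 13 and 1 without the 3 largest libraries. Single transcripts with the block gave 28 and 1. Array weights gave 101 and 1441; their estimation stopped before it converged, with weights from 0.149 to 24.4. Without 1 library each, the counts were 3 to 5 higher and 0 to 1 lower, with 1 lower only without virgin replicate 4.

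Kmt5a missed the threshold in every alternative, and its log2 fold change of −0.37 ran from −0.85 to 0.19 without 1 library each, turning positive without GD14.5 replicate 1. It was also positive with the block on equal medians (0.02), without the 3 largest libraries (0.05) and with the covariate (0.16). The transcript was at 0.08 FPKM in virgin replicate 1 and 0.04 in GD14.5 replicate 1, against 1.38 or more in the other libraries. Leaving out either of these libraries moved the fold change the most. Why they were low, and why the sign turned in the other fits, was not tested. The methyltransferase list stayed uncalled. The acinar covariate and the scaling without acinar markers and hormones were not run, since those genes are not analysed here. The unknown depth sets no floor for loci listed at 0.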

Other observations

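The tests of library scaling and of chance for the loci at or beside pregnancy and lactogen genes, and the limits of these tests, were chosen after the result was seen. The tests on Kirrel3 transcripts and on coding reads were set before theirs, while the count of loci under coding names, and the counts of Kirrel3 transcripts without the minimum or with it on virgin libraries, were added after.

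Noncoding loci beside beta cell identity genes did not pass the threshold. Plut, beside Pdx1 on chromosome 5 (147228598 to 147271521), was at 8.67 ± 6.13 FPKM in virgin islets (SD, n = 5) and 4.53 ± 2.46 at GD14.5 (SD, n = 4), with a log2 fold change of −0.69 ± 0.55 (SE; limma adjusted p = 0.817). Paupar and Pax6os1, beside Pax6, had −0.44 ± 0.46 and −0.55 ± 0.53, and Pcsk2os1, beside the prohormone convertase gene Pcsk2, had −0.34 ± 0.52 (SE), against a median of −0.30 over all loci. With the replicate block the values of Plut, Paupar, Pax6os1 and Pcsk2os1 were −0.38, −0.26, −0.26 and −0.09.

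Of the 6 classes of loci, 5 were not called by camera without or with the replicate block. Without it, the adjusted p was 0.151 for 18 snoRNA host genes, 0.206 for 5 microRNA host genes, 0.336 for 57 loci named as the opposite strand of a coding gene, 0.703 for 8 imprinted noncoding RNAs and 0.851 for 9 nuclear and X-inactivation RNAs. With it, the adjusted p was 0.0955, 0.260, 0.165, 0.747 and 0.747. Among the snoRNA hosts, Gas5 stood at 50.7 ± 34.7 and 53.0 ± 29.0 FPKM and Snhg3 at 62.3 ± 22.1 and 69.4 ± 17.7. The 579 loci with the name of a coding gene had a median log2 fold change of −0.25, against −0.30 over all loci, and 121 were above 0. They thus lay less far below 0 than the others (camera adjusted p = 0.0147), which the block ended (0.0702). With an estimated correlation of 0.561 without the block, the adjusted camera p was 0.947.

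The loci at or beside genes of the pregnancy and lactogen list included 4 of 6 called higher with the block. With the block and an estimated correlation the set was not called (camera adjusted p = 0.0661). The estimated correlation there was −0.0434, below the preset 0.01. The mean difference of the 6 loci over the same-numbered pairs was 1.74 on the log2 scale as deposited and 1.85 with equal library medians, from 1.56 to 2.17 in the 4 pairs. Equal medians thus did not lower it. Differences within pairs leave out replicate batches by construction, so the test does not decide on these. Ivd and Cish, seen before the set was chosen, weighed most, with blocked log2 fold changes of 4.16 and 3.10. The values were 1.62 at 5730420D15Rik, 1.60 at 1300002E11Rik, −0.03 at Gm41269 and 0.01 at Sergef. Fisher's exact test, with 4 of 6 list loci and 19 of 2371 others higher with the block (p = 9.88e-08; without Ivd and Cish 2 of 4, p = 4.42e-04), does not settle chance for this set, because it treats loci as independent and the set was chosen after the leading loci had been seen. Reads of the coding gene's own messenger RNA or its precursor counted at the locus cannot be told apart from a noncoding transcript, since 3 of the 6 loci, Ivd, Cish and Sergef, are transcripts of unknown identity under a coding gene's name. A rise of the coding genes themselves therefore stays open.

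The 3 loci inside Kirrel3 were higher at GD14.5 with the block. To ask whether only 1 transcript carries the rise, transcripts higher in all 4 same-numbered pairs were counted. These were 7 of their 8 transcripts with a mean FPKM of at least 0.5, above the share set in advance. The rise itself can carry a transcript past this mean. Of the 5 with a virgin mean of at least 0.5, 3 were higher in 4 pairs, and of all 18 transcripts 12 were. These shares fall short of the one set in advance, so the test does not decide, though more than 1 transcript was higher. The exception among the 8 was a transcript of Kirrel3os at a mean of 1.87 FPKM in virgin and 1.62 at GD14.5 libraries. Whether the signal is intronic Kirrel3 precursor was not tested.

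Some transcripts followed the replicate number or 1 library. One transcript of Neat1 was at 17.7 FPKM in virgin replicate 1 and 18.1 in GD14.5 replicate 1, and at 0.03 or less in the other 7 libraries. Vaultrc5, a vault RNA gene, was at 59.0 to 74.96 FPKM in numbers 2 and 3 of both groups, and at 4.14 to 8.46 in numbers 4 and 5. Gm51621 was listed at 0.02 FPKM in GD14.5 replicate 1 and at 276 to 1115 FPKM in the other 8 libraries. After library medians were set equal, 667 of the 2377 loci differed between the 3 sets of numbers in a limma fit with the group as a term. The sets were chosen from the values of these same libraries, so this count is in part what the choice selects.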
